A study of Homo sapiens with 12 samples.

How the data were processed

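Poly(A)-selected RNA of HepG2 cells was sequenced in 12 libraries, 3 for each of the 4 shRNA groups. Per the labels, 2.5 M cells (M, for mega) were seeded on 10 cm dishes 2 days before RNA isolation, and libraries were made with a kit that keeps strand. The submitters' processing notes name Trim Galore, STAR, Subread and DESeq2 and the build GRCh37, with no versions or roles. The files hold 3 tables of splice-junction events, 2 tables of exon bins and 1 table of mapping statistics. All coordinates are those of the files, in GRCh37.

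The junction tables hold inclusion as a fraction, with 1 column for the control and 1 for the knockdown, per the file headers. These columns carry the name of the first library of each group, and whether a value stands for that library or for all 3 is not stated; it is read here as the value of the group. They also hold the authors' expected difference in inclusion and, at a probability of 0.95, the minimum difference, per the file headers, whose form is that of vast-tools. Inclusion is printed here in percent and its difference in percentage points. All listed events had an absolute difference of at least 10 points, and a minimum difference of at least 1 point, so events under these limits were not analysed here. Event types were read from the identifiers. The exon tables hold a mean normalised signal per bin, a log2 fold of usage, p-values with adjusted p-values, and read counts per library, deposited by the authors; the headers have the form of DEXSeq output. The log2 fold is control over knockdown per the file headers and was turned so that positive values mean higher usage after knockdown. In the RARS1 table the turned sign was checked against the counts and matched in 94.6% of bins. The SRRM2 sign could not be checked on counts of labelled control libraries. Both tables also hold a usage value for each condition, under the same name for the control, and the turned fold matched their difference in all 985 RARS1 and all 41637 SRRM2 bins with a fold. The change of the rest of a gene was taken as the log2 change in normalised count less that in usage; in 76 genes outside merged loci with at least 2 listed bins of a mean count of at least 10 it was nearly the same for each bin of a gene (SD 0.01 within genes, 0.41 between genes). This step was added after the results were seen. Size factors recovered from the deposited counts and mean normalised signal of the RARS1 table (0.875 to 1.22) gave the normalised counts. The mapping table gives read counts and the uniquely mapped share per library as a fraction of 0 to 1 per the values, although the column is named in percent, per the file headers.

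Both exon tables list only bins with an adjusted p under 0.05, so the number of bins tested was recovered from the adjusted p-values. In 2 and 60 places a long transcript list ran onto an extra line, and 13 and 422 repeated rows were removed from the RARS1 and SRRM2 tables. Among the SRRM2 counts, 3 columns matched no library label and were used in no step. Genes that overlap were joined into 1 locus in the deposited tables. Transcript identifiers were looked up in GENCODE 29, by identifier only, to name the gene that holds a bin.

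Because of this cut, the refit of exon usage planned before the data were examined was not possible, and the authors' adjusted p-values are the main result. For the same reason no fit with a replicate block or with other normalisation, no other split of the libraries and no count adjusted over the list alone could be made. Directions were tested with the exact binomial test and differences between groups of events with Fisher's exact test, both two-sided, and mapping statistics with exact permutation tests over 12 comparisons. P-values were adjusted by Benjamini-Hochberg within each family. Intervals are 95% Clopper-Pearson intervals, which cover counting error only. The background of gene overlaps is the genes in either exon table, with each gene of a merged locus counted, and that of bin overlaps is the smaller number of bins tested. For shared controls, the chance overlap of unchanged groups was integrated with a correlation of 0.5 between comparisons. RARS1 gene lists were tested against 10000 random lists matched on deciles of the number of bins listed after SRRM2 knockdown and, within those, on mean count above or under the median, a coarser match than the planned deciles. SRRM2 lists, against the plan, were tested for the share of bins with higher usage against 10000 lists matched on the number of listed bins, since no set of tested genes was available.

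The 15 gene lists and the naming rule were fixed before the data were examined. The rule takes the targeted genes, the 10 largest increases and 10 largest decreases of each table with 1 event or bin per gene and a mean count of at least 50 for bins, up to 4 members of each list by smallest adjusted p, and up to 10 genes found in at least 2 junction tables. INCENP, CDK5RAP3, CHEK2, CLK2, SRSF5, CSNK1D, SLC6A8, HOMER3, MVP, the other genes of merged loci and the list members named in the junction tables were chosen after their values were seen.

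Library titles carry numbers that match between the control and RARS1 groups. Over the listed RARS1 bins, same-numbered libraries deviated together from their group means (r = 0.348, 0.231 and 0.308 across bins, which are not independent). The numbers were therefore taken to pair the libraries. All other pairs had r under 0 (-0.0419 at most), but deviations from a group mean sum to 0, so this is not separate evidence. Steps over many bins or genes were tested on simulated data. The number of tests and the size factors were recovered, 43.5% of RARS1-like lists of 40 genes with 4 planted genes among 8600 passed an unadjusted p of 0.05, all with 8 passed, and 2% with none passed. The direction test passed 8.5% of SRRM2-like lists without a planted shift, somewhat over the nominal 5%, and all lists with a log2 shift of 0.5; the share without a shift varied when the simulation was rerun with other random draws. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.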

Results

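Splicing and exon usage were measured by poly(A) RNA sequencing in HepG2 cells, a line derived from a human liver tumour. Cells expressed a non-targeting control shRNA or an shRNA against 1 of 3 genes. RARS1 (listed as RARS) encodes arginyl-tRNA synthetase, MARS1 (listed as MARS) encodes methionyl-tRNA synthetase, and SRRM2 encodes a large protein with serine and arginine repeats that is associated with the spliceosome. Each of the 4 groups held 3 libraries. The labels do not say whether replicates came from separate cultures, so p-values over libraries measure only the spread between these libraries, which may be technical. Uniquely mapped reads (M, for mega) averaged 74.7 M ± 9.19 (SD, n = 3) in the control, 70.3 M ± 5.97 (SD, n = 3) after RARS1 knockdown, 63.0 M ± 10.8 (SD, n = 3) after SRRM2 knockdown and 65.6 M ± 5.24 (SD, n = 3) after MARS1 knockdown. Against the control this depth gave p = 0.7, 0.3 and 0.3 for RARS1, SRRM2 and MARS1 knockdown (exact permutation test, two-sided, adjusted p = 0.7, 0.6 and 0.6), where 0.1 is the smallest p possible, so a difference in depth is not excluded. The uniquely mapped share was 89.3% ± 0.547 (SD, n = 3) in the control, 89.6% ± 0.549 (SD, n = 3) after RARS1 knockdown, 86.9% ± 0.823 (SD, n = 3) after SRRM2 knockdown and 86.9% ± 1.30 (SD, n = 3) after MARS1 knockdown. Trimming removed 0.0629% to 0.0910% of reads in the 6 control and RARS1 libraries and 0.517% to 2.90% in the 6 SRRM2 and MARS1 libraries. For both measures the SRRM2 and MARS1 differences from the control gave p = 0.1 (exact permutation test, two-sided, adjusted p = 0.3), the smallest p that 3 libraries against 3 allow.

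**Figure D1:**
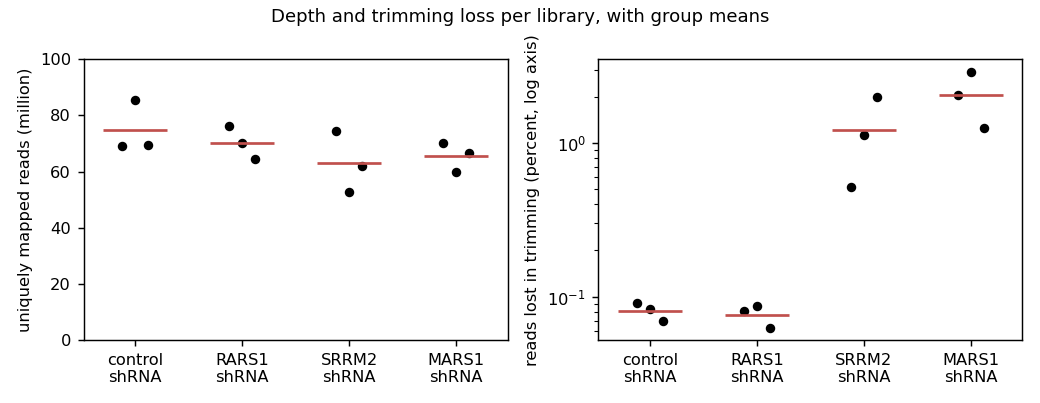
Uniquely mapped reads in M reads (left) and the percent of reads lost in trimming on a log axis (right), with 1 point per library and a line at the mean of each group of 3. All 6 SRRM2 and MARS1 libraries lost at least 0.517% of their reads and all 6 control and RARS1 libraries at most 0.0910%.

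After RARS1 knockdown the retained introns in the junction table rose and most cassette exons fell. The authors' deposited table shows inclusion of a retained intron rising from 8.52% to 31.5% in TNS4, which encodes a focal adhesion protein, and from 24.1% to 44.3% in PLEKHG5. The same table, the authors' deposited table of junctions, lists a cassette exon of the axonemal dynein gene DNAH17 at 76.4% in the control and 53.1% after knockdown. A cassette exon of FAM126A rose from 34.2% to 53.9% in the authors' deposited table. Over all types, 41 events in 40 genes were listed, 24 with higher and 17 with lower inclusion.

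All 16 retained introns had higher inclusion after RARS1 knockdown (100%, 95% Clopper-Pearson interval from 79.4%, exact binomial p = 3.05e-05, adjusted p = 0.000122). Of 24 cassette exons, 7 rose and 17 fell, a split that did not pass the test (exact binomial p = 0.0639, adjusted p = 0.110). Retained introns and cassette exons differed in direction (Fisher's exact test, p = 6.69e-06). Retained introns also rose in FGFR3, a fibroblast growth factor receptor, from 22.4% to 38.7%, in TMEM106A from 30.7% to 46.9% and in MYO6 from 6.67% to 21.2%, by the authors' deposited table. Those of ENO2, the neuronal form of enolase, and of CUL9 rose by 13.5 and 13.4 percentage points in the authors' deposited table. A cassette exon of KIAA1217 rose from 12.8% to 26.7%, and an alternative splice site of NT5C2 from 40.4% to 56.5%, in the authors' deposited table. Cassette exons fell in ISL2 (95.9% to 77.3%), ZNF232 (61.2% to 43.5%), SLC25A23 (85.8% to 71.4%) and C17orf56 (73.9% to 59.7%) in the authors' deposited table. In IL6R, the interleukin 6 receptor, and DDX58, the cytosolic RNA sensor also named RIG-I, exons fell from 89.0% to 74.8% and from 97.9% to 85.6% in the authors' deposited table. Exons of STX2 and PSD4 fell from 57.0% to 43.3% and from 82.6% to 70.5% in the authors' deposited table. Changes were moderate, with only 3 of the 41 events moving by 20 percentage points or more. The table gives 1 inclusion value for the control and 1 for the knockdown, in columns named for the first library of each group. It does not state whether a value stands for that library or for all 3, so no spread over libraries could be given. The tests of direction over events or bins, here and for the other knockdowns, count these as independent. Their p-values do not measure the spread between libraries or cultures. The minimum difference at a probability of 0.95 was small for the largest changes, at 1 point for TNS4 and DNAH17 and 2 points for PLEKHG5. It was 5 points for FAM126A and 6 points for the FGFR3 intron.

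After SRRM2 knockdown the direction of both main event types was the other way: retained introns fell and cassette exons rose. The authors' deposited table gives inclusion of an intron of OGT, which encodes the enzyme that attaches O-linked N-acetylglucosamine to proteins, at 84.7% in the control and 36.9% after knockdown. An intron of FYTTD1, an mRNA export adaptor, fell from 65.6% to 19.5% in the authors' deposited table. A cassette exon of TNRC6A, a partner of Argonaute proteins in silencing, rose from 54.1% to 89.1% in the authors' deposited table. There were 345 listed events in 295 genes, 146 with higher and 199 with lower inclusion.

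Of 156 retained introns 144 fell and 12 rose (7.69% higher, 95% interval 4.04% to 13.1%, exact binomial p = 6.70e-30, adjusted p = 8.04e-29). Of 159 cassette exons 122 rose and 37 fell (76.7% higher, 95% interval 69.4% to 83.1%, exact binomial p = 8.43e-12, adjusted p = 5.06e-11). Alternative splice sites split into 12 higher and 18 lower in 19 genes; some are competing sites of a single choice, so no test is read from this balance. Further introns in the authors' deposited table fell by 44.0 points in C8orf73, 42.9 points in CCDC14, 38.6 points in CCDC57, 37.2 points in SLC22A18 and 36.8 points in STAMBP, a deubiquitinating enzyme. Introns of CALML4, BOLA1 and ARMCX3 fell from 42.5% to 6.94%, from 60.1% to 25.7% and from 78.2% to 44.2% in the authors' deposited table. The minimum difference at a probability of 0.95 was 33 points for the OGT intron and 2 points for that of ARMCX3. Exons rose in the cytoskeletal linker MACF1 (25.9% to 56.8%), the kinase MAP3K7 (24.8% to 55.1%), KIAA1217 (12.8% to 43.0%) and ARHGEF10L (48.4% to 78.2%) in the authors' deposited table. The exons of BAT2D1, GPER, MATR3 and SHROOM1 rose by 27.2, 26.6, 26.2 and 25.7 points in the authors' deposited table. An intron of EIF2C4, the gene of Argonaute 4, went against the other introns and rose from 4.16% to 31.6% in the authors' deposited table. Of the fixed lists, adhesion and cytoskeleton genes held 13 events in 11 genes (7 higher, 6 lower), among them FN1, ITGA6, CTNND1 and TJP1. Membrane trafficking held 6 events in 4 genes, DNM1L, PICALM, SEC31A and STX16, all higher. In the list of SR proteins and their kinases an intron of the kinase gene CLK2 fell from 46.4% to 23.9% and one of LUC7L3 from 46.3% to 30.2% in the authors' deposited table. Of the hnRNP genes, a cassette exon of HNRNPA2B1 fell from 60.9% to 41.1% in the authors' deposited table. No core spliceosome, ribosomal protein or synthetase gene was listed in this table.

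After MARS1 knockdown introns of the targeted gene itself had higher inclusion. Inclusion is a relative value, and no exon bin counts were available for this knockdown. A change in the amount of MARS intron sequence was therefore not shown. The authors' deposited table lists a pair of MARS introns, which rose from 3.05% to 37.8% and from 1.45% to 24.1%. Retained introns as a class fell and cassette exons rose, as after SRRM2 knockdown. By the authors' deposited table an intron of C8orf44 fell from 73.8% to 34.6%, and one of PIGT, a subunit of the GPI transamidase, from 75.7% to 41.0%. The minimum difference at a probability of 0.95 was 24 and 11 points for the MARS introns, but 3 points for C8orf44 and 1 point for PIGT. The 147 listed events lay in 131 genes, 70 with higher and 77 with lower inclusion.

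Of 65 retained introns 49 fell and 16 rose (24.6% higher, 95% interval 14.8% to 36.9%, exact binomial p = 5.08e-05, adjusted p = 0.000153). Of 71 cassette exons 50 rose and 21 fell (70.4% higher, 95% interval 58.4% to 80.7%, exact binomial p = 0.000767, adjusted p = 0.00184). Among events that moved by 20 points or more these splits no longer passed the test, with 8 of 21 introns (exact binomial p = 0.383) and 9 of 13 exons (exact binomial p = 0.267) higher. Introns that rose beside those of MARS were in MTMR9 (9.75% to 48.8%), in MASP2, a complement protease made in liver (8.80% to 46.9%), in the transporter gene ABCC3 (36.3% to 70.7%) and in DNAH17 (3.02% to 25.5%), by the authors' deposited table. Exons of FAM126A and ANKRD13D rose by 33.3 and 32.0 points, and those of SOCS7, SHROOM1 and MALT1 by 24.4, 22.5 and 22.1 points, in the authors' deposited table. Introns of CALML4, STAMBP, SFRS18, FBXO9, RUFY3 and KREMEN2 fell by 28.2, 26.7, 24.4, 23.4, 23.3 and 22.5 points in the authors' deposited table. Exons of SUGP2, a gene with a splicing factor domain, and JOSD2 fell from 94.7% to 66.8% and from 93.9% to 71.2% in the authors' deposited table. In SRSF5, an SR protein gene, an intron fell from 55.0% to 36.4% in the authors' deposited table.

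**Figure D2:**
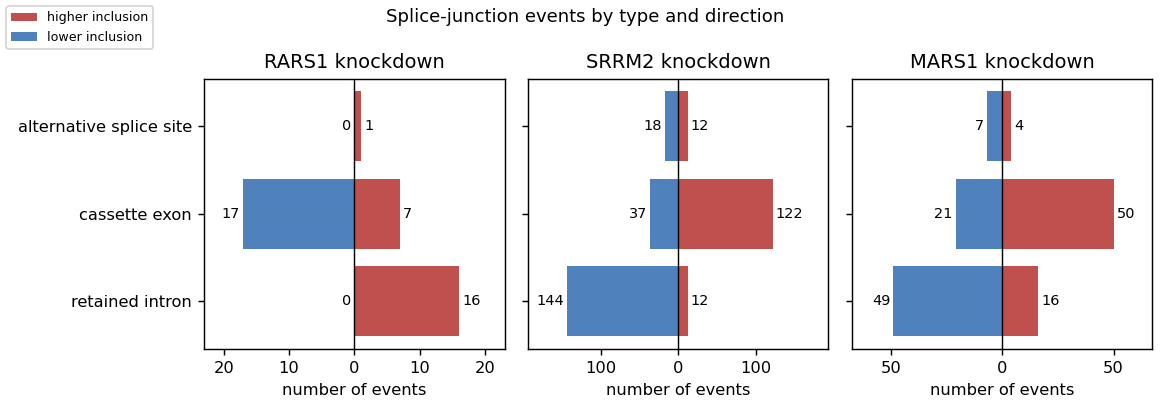
Number of splice-junction events with higher (red, right) and lower (blue, left) inclusion after each knockdown, by event type, on a separate scale for each knockdown. Retained introns were 16 higher and 0 lower after RARS1, 12 and 144 after SRRM2, and 16 and 49 after MARS1 knockdown.

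The junction tables of SRRM2 and MARS1 shared more genes and events than the other pairs. Introns of CALML4, STAMBP, FBXO9, KREMEN2 and FTCD, a liver enzyme of histidine breakdown, fell after both knockdowns, and a cassette exon of SHROOM1 rose after both. In the authors' deposited table the intron of FTCD stood at 42.8% in the control and 16.7% after SRRM2 knockdown, and at 43.0% and 22.1% in the MARS1 comparison. An exon of the checkpoint kinase gene CHEK2 rose from 44.9% to 64.3% after SRRM2 and from 44.2% to 65.7% after MARS1 knockdown in the authors' deposited table. Of 46 events listed in both, 45 changed in the same direction, as nearly all would for unchanged groups with the same controls. The exception was a cassette exon of FGFR3, which the authors' deposited table gives at 33.5% after SRRM2 knockdown and 65.1% after MARS1 knockdown, against 44.8% and 44.5% in the control.

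The RARS1 and SRRM2 tables shared 6 events, of which 1 changed in the same direction. Introns of CDK5RAP3, ENO2 and TMEM106A rose after RARS1 knockdown and fell after SRRM2 knockdown. The authors' deposited table lists the ENO2 intron at 52.1% after RARS1 and 19.7% after SRRM2 knockdown. Inclusion of an exon of INCENP, a subunit of the chromosomal passenger complex, was 19.6% after RARS1 and 51.3% after SRRM2 knockdown in the authors' deposited table. The FGFR3 exon also went in opposite directions, and the exon of KIAA1217 rose after both. The RARS1 and MARS1 tables shared 5 events, among them events in FOXM1, FGFR3 and FAM126A, all 5 in the same direction. Counted by genes among 10500 background genes, SRRM2 and MARS1 shared 49, against 3.14 for independent lists (Fisher's exact test, two-sided, p = 9.01e-47, adjusted p = 2.70e-46). RARS1 and SRRM2 shared 9 against 0.976 (Fisher's exact test, adjusted p = 5.31e-07), and RARS1 and MARS1 shared 6 against 0.419 (Fisher's exact test, adjusted p = 3.26e-06). All 3 tables use the same control libraries, and unchanged groups with lists of these lengths would share 21.8, 8.90 and 5.35 genes for these pairs. With 3 control libraries no split into parts of at least 2 libraries was possible, so the shared controls alone could give the number RARS1 shares with MARS1 and part of that of SRRM2 and MARS1. They would move shared events the same way, so they do not account for the events in which RARS1 and SRRM2 knockdown were opposite.

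**Figure D3:**
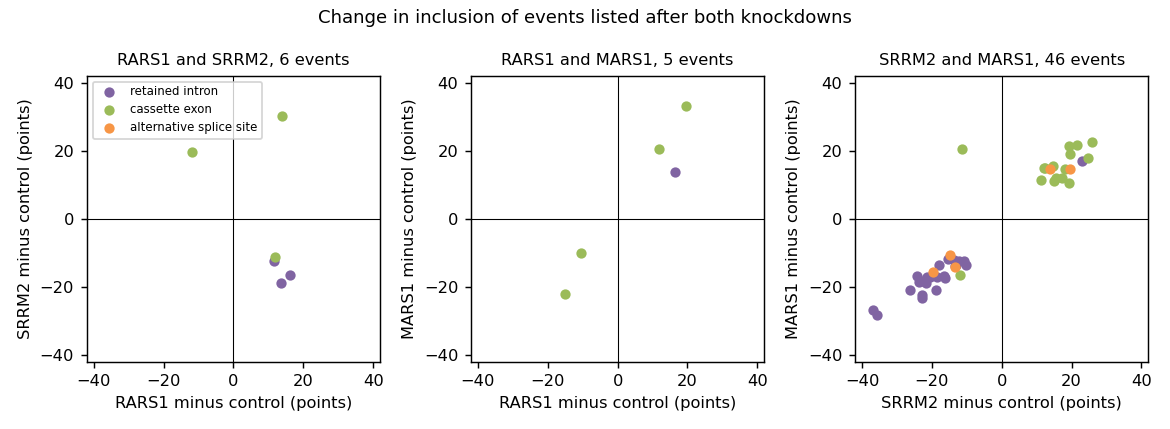
Change in inclusion in percentage points for each event listed after both of 2 knockdowns, coloured by event type. The SRRM2 and MARS1 panel holds 46 events, 45 of them in the quadrants of equal direction, and the RARS1 and SRRM2 panel holds 6, with 1 in those quadrants.

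Exon usage compares the reads of an exon bin, a stretch of exon sequence between annotated boundaries, with those of the rest of its gene. After RARS1 knockdown the largest rise among bins with a mean count of at least 50 was in RARS itself. In the authors' deposited table, usage of the bin at chromosome 5, 167921742 to 167922156 (GRCh37), held by 1 annotated transcript, rose by 2.06 on the log2 scale (adjusted p = 6.99e-11). Its normalised read count was 39.9 ± 7.73 (SD, n = 3) in the control and 69.8 ± 26.0 (SD, n = 3) after knockdown. The other 3 listed RARS bins rose by 1.41 to 1.83 in the authors' deposited table, while bins shared by most RARS transcripts were not listed. Usage is relative to the rest of the gene, and in all 4 bins the log2 change in count less that in usage lay between -1.26 and -1.24, which puts the rest of RARS lower by that log2 amount after knockdown. A bin of TFPI, the tissue factor pathway inhibitor, rose from a normalised count of 1383 to 3741 and by 1.63 in log2 usage in the authors' deposited table (adjusted p = 2.78e-09). A bin of UQCC2, an assembly factor of respiratory complex III, fell from 576 to 231 normalised counts, with a log2 usage of -1.91 in the authors' deposited table (adjusted p = 0.000149).

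In all, 989 bins in 533 genes were listed after RARS1 knockdown, 0.281% of 351451 bins tested, with 514 higher, 471 lower and 4 without a fold (52.2% higher, exact binomial p = 0.181). Bins held by 1 transcript were higher in 216 of 285 cases and bins of more transcripts in 42.6% of cases (Fisher's exact test, p = 6.38e-22). At a mean count of at least 50, further rises in the authors' deposited table were in CSDC2 (1.81), FHL2 (1.68), PAGR1 (1.34), the hypoxia-responsive gene NDRG1 (1.34), the tubulin gene TUBB6 (1.33), ARHGAP17 (1.22), GPRC5C (1.20) and GIGYF2 (1.18), all as log2 usage. For CSDC2, FHL2, NDRG1 and TUBB6 the counts of the control and knockdown libraries overlapped. Mean normalised counts were 744 in the control and 860 after knockdown in CSDC2, and 2242 and 2716 in TUBB6. The bins of PAGR1, ARHGAP17 and GIGYF2 lay in loci where overlapping genes were counted as 1. Among bins with a mean count of at least 50, the largest other falls in the authors' deposited table were in LYPLAL1 (-1.51), NBL1 (-1.37), MXD1 (-1.31), the tropomyosin gene TPM1 (-1.24), C16orf45 (-1.22), PSME2 (-1.14), DISC1 (-1.02), UBXN11 (-1.01) and PCSK7 (-0.93), as log2 usage. The bins of NBL1, MXD1, C16orf45 and DISC1, and that of UQCC2, lay in such joined loci, where usage is relative to more than 1 gene. Counts moved with usage: the mean normalised count changed in the direction of the usage in 932 of 985 bins (94.6%), and the 3 libraries of each group did not overlap in that direction in 724 (73.5%, against 5% by chance for bins not chosen by a test). Of the 989 bins, 467 (47.2%) lay in loci where overlapping genes were counted as 1. Among the 522 others 59.8% were higher ( exact binomial p = 9.25e-06).

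In many of those loci the listed bins of neighbouring genes differed in direction. The 12 listed bins of MXD1, a partner of MAX, were all lower in usage and summed to 2953 ± 262 normalised counts in the control and 1545 ± 137 after knockdown, while the 8 of its neighbour SNRNP27 were all higher and summed to 4012 ± 279 and 5230 ± 467 (SD, n = 3 each). The 19 PIK3C2A bins, all lower, summed to 6612 ± 410 and 5057 ± 115, and the 2 bins of the ribosomal gene RPS13, both higher, to 27430 ± 2932 and 37741 ± 4912 (SD, n = 3 each). In the same way all 17 bins of ARAP1 were lower and all 4 of STARD10 higher, and all 8 of SYVN1 lower and all 3 of FAU higher. These sums hold only bins listed for their usage, so they are not the expression change of the gene. In 18 merged loci at least 3 bins were assigned to a single gene each and to at least 2 genes in all. The bins split by gene in 17 of these loci, against a median of 2 and a maximum of 7 in 1000 shuffles of the directions (permutation p = 0.001, the smallest these shuffles can give). The shuffles treat bins of the same gene as independent, so this p does not measure evidence over loci. With at least 2 such bins 21 of 24 loci split. MVP, the main protein of vault particles, held 18 listed bins, 14 of them lower, with summed normalised counts of 5816 ± 1107 in the control and 2689 ± 288 after knockdown (SD, n = 3 each).

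**Figure D4:**
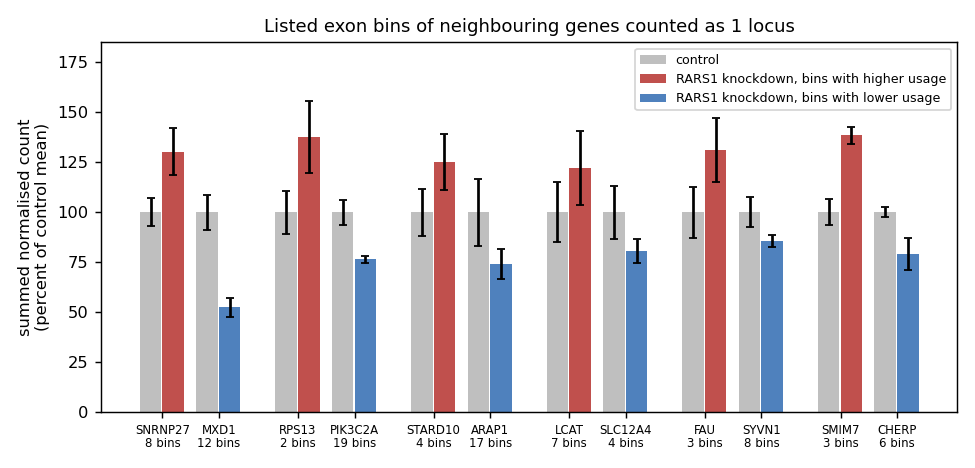
Normalised counts summed over the listed exon bins of each gene, as percent of the control mean, for 6 pairs of neighbouring genes counted as 1 locus; bars are means and error bars SD over 3 libraries. In each pair 1 gene, such as SNRNP27, had only bins with higher usage after RARS1 knockdown and the other, such as MXD1, only bins with lower usage, and only these listed bins are summed.

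The fixed gene lists were small contributors after RARS1 knockdown. None of the 15 passed the test against 10000 matched random lists (permutation test, 2 lists at an unadjusted p under 0.05). List members are counted out of those found in either exon table (8624 genes, each merged locus counted once), not out of all tested or expressed members. Adhesion and cytoskeleton genes with known alternative exons came closest, with 11 of 45 genes listed against 4.64 in matched lists (permutation p = 0.00840, adjusted p = 0.126). Fisher's exact test without matching gave an adjusted p = 0.00101 for this list and 0.0457 for ribosomal proteins (9 of 55 genes, adjusted p = 0.285 with matching). With merged loci left out, the adhesion list held 10 of 43 genes (permutation, adjusted p = 0.0420). Its members in the authors' deposited table include TPM1, CAST (-0.66), FGFR3 (0.61) and CTNND1 (-0.14), as log2 usage. Of ribosomal genes RPS15A (0.08), RPL36A (-0.61, a bin held by its neighbour HNRNPH2), RPL37 (-0.63) and RPL8 (0.68) were listed in the authors' deposited table. Of the 27 bins of this list 7 were higher and 20 lower, and 18 lay in merged loci. Hepatocyte genes had 6 of 31 listed (permutation, adjusted p = 0.354), among them ALB (-0.05) and SERPINA1 (0.03) in the authors' deposited table. Of cholesterol and fatty acid genes 4 of 28 were listed (permutation p = 0.333), among them LSS (0.81), FDPS (0.47) and CYP51A1 (0.11), each higher in the authors' deposited table. DNA repair genes (4 of 34, ATM, FANCD2, XRCC5 and CHEK1, the last through a bin held by its neighbour STT3A) and cell cycle genes (3 of 39, MCM4, CDKN1A and MCM2) had only higher bins, and both adjusted permutation p values were 1. Synthetases had 2 of 20 genes listed (RARS and VARS), hnRNP genes 2 of 17 (HNRNPH1 and PTBP3), core spliceosome genes 3 of 39 (PRPF3, SNRNP200 and SF3A2), export and decay genes 1 of 23 (CASC3) and trafficking genes 3 of 42 (AP2A2, CLTC and COPE, the last through bins of its neighbour HOMER3 and a bin of its own). No SR protein gene (0 of 25), ATF4 target (0 of 19) or inflammatory gene (0 of 26) was listed, and of markers of other cell types 1 of 5 was, TAGLN at a mean count of 4.52 in the authors' deposited table.

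After SRRM2 knockdown exon usage changed far more widely, with more bins lower than higher. In SRRM2 itself, which overlaps another gene in the table so that its values are uncertain, 20 listed bins were lower, between 2808471 and 2818997 of chromosome 16 (GRCh37), and 16 were higher, between 2817508 and 2822539. The authors' deposited table gives a log2 usage of -0.72 for its bin at 2818601 to 2818746 (adjusted p = 1.29e-19), and of 0.90 for the bin at 2820356 to 2820466 (adjusted p = 0.000294). Among bins with a mean count of at least 50, the largest fall was in SUB1, a transcriptional coactivator, at -3.23 log2 usage in the authors' deposited table (adjusted p = 5.67e-15). A bin of FTCD fell to -2.60 with an adjusted p = 1.28e-93, and bins of IGF2 and of the serine and glycine enzyme gene SHMT2 were at -2.53 and -2.37, in the authors' deposited table.

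In all, 41718 bins in 8572 genes were listed, 12.1% of 344909 tested, with 15834 higher and 25803 lower (38.0% higher, 95% interval 37.6% to 38.5%). At that mean count, further falls in the authors' deposited table were in TMEFF1 (-2.81), AC007319.1 (-2.60), CCDC24 (-2.47), HNRNPD (-2.34), TSPAN14 (-2.34) and the splicing regulator gene TRA2B (-2.28), as log2 usage. The largest rises at that mean count in the authors' deposited table were in RP11-517H2.6 (3.21), ZCCHC2 (2.44), NHLRC4 (2.39), DMWD (2.37), GLIPR1 (2.33), SLC39A14 (2.33), PTAR1 (2.32), CHKA (2.26), MARS (2.25) and the receptor gene ERBB2 (2.24), as log2 usage. The bin of RP11-517H2.6 was held by transcripts of CCR6 and Z94721.2. That bin and those of NHLRC4, DMWD, TMEFF1 and IGF2 lay in joined loci, where usage is relative to more than 1 gene. Of 14 listed MARS bins 12 were higher, and of 11 RARS bins 9 were lower. Bins of 1 transcript were higher in 2911 of 10051 cases and other bins in 40.9% (Fisher's exact test, p = 3.34e-105). Among genes with a falling retained intron in the junction table, 252 of 280 such 1-transcript bins were lower (90%), against 70.5% in other genes (Fisher's exact test, p = 8.55e-15). These 280 bins came from 98 genes, and the test counts bins of 1 gene as independent. The control columns of this table carry names that match no library label, so counts per library were not used, and no spread is given.

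**Figure D5:**
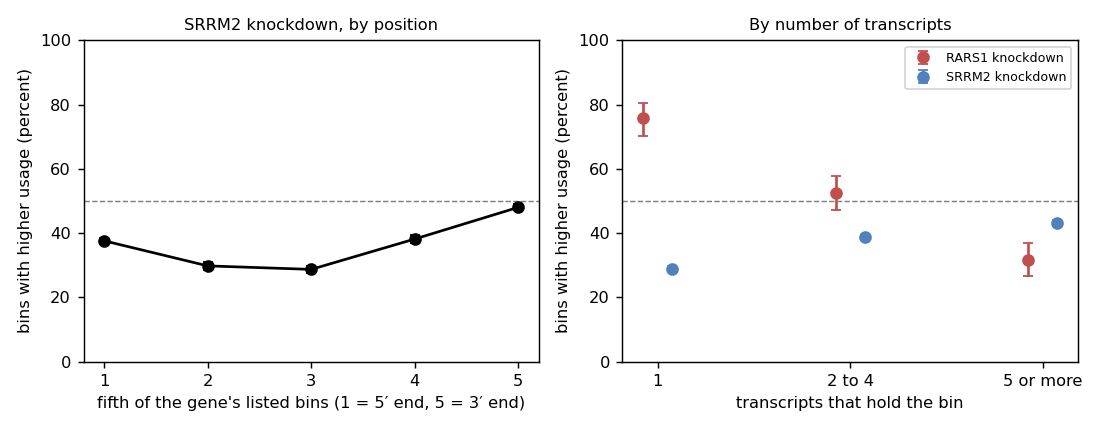
Percent of listed exon bins with higher usage, with 95% Clopper-Pearson intervals. Bins are set by rank among the listed bins of their gene after SRRM2 knockdown (left). On the right they are set by the number of transcripts that hold the bin, after either knockdown. The dashed line marks 50%. Bins of 1 transcript were higher in 216 of 285 cases after RARS1 and 2911 of 10051 after SRRM2 knockdown.

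Members of all 15 fixed lists were listed after SRRM2 knockdown, and no list differed in direction from matched random gene lists (permutation test over 10000 lists, 2 lists at an unadjusted p under 0.05). Synthetases had 77 of 153 bins higher in 20 genes (50.3% against 37.9% in matched lists, permutation p = 0.0272, adjusted p = 0.293), and 46.8% without MARS. ATF4 targets had 60 of 115 bins higher (52.2%, permutation p = 0.0444, adjusted p = 0.293), with log2 usage of -1.55 for SLC1A5, 0.50 for VEGFA and 1.11 for ASNS in the authors' deposited table. Ribosomal proteins had 30.8% of 260 bins higher (adjusted p = 0.293), and RPS20 (-0.60), RPL12 (-0.50), RPLP0 (-0.59) and RPS2 (-0.49) had the smallest adjusted p values of the list in the authors' deposited table. Cell cycle genes had 30.0% of 207 bins higher (adjusted p = 0.293), with MKI67 (-0.89), AURKB (-1.15), CDK4 (0.55) and BUB1B (0.85) in the authors' deposited table. SR proteins and kinases had 36.1% of 288 bins higher, hnRNP genes 37.4% of 262, core spliceosome genes 39.6% of 235, and export and decay genes 31.6% of 152. In these lists the authors' deposited table gives LUC7L3 (-0.85), SRSF7 (-1.36), SRRM1 (-2.15), HNRNPA2B1 (-0.61), SNRPB (0.12), PRPF6 (0.27), THOC5 (-0.41) and THOC2 (-2.09). The bins of SNRPB and THOC5, and those of RPS20, RPS2 and BUB1B, lay in joined loci. Cholesterol and fatty acid genes had 40.3% of 186 bins higher, hepatocyte genes 36.6% of 161, DNA repair genes 35.7% of 266, adhesion and cytoskeleton genes 39.0% of 482, trafficking genes 32.6% of 353, inflammatory genes 39.0% of 136 and markers of other cell types 42.9% of 28. Examples from the authors' deposited table are FASN (0.24), MVK (-1.20), FDFT1 (-2.25), SERPINA1 (1.32), HNF4A (-0.99), NUMA1 (0.48), ACTN4 (-1.90), VAMP2 (1.02), IKBKG (-0.55), LYZ (-1.33) and PDGFRB (1.21).

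In both exon tables bins of CSNK1D, a casein kinase, rose, by 0.81 after RARS1 and 1.88 after SRRM2 knockdown in the authors' deposited table, and those of HOMER3 fell. In the RARS1 comparison HOMER3 lay in a locus joined with COPE, so its lower usage is relative to both genes. The 2 tables shared 319 bins, 32.3% of the RARS1 bins, against 120 for independent lists (Fisher's exact test, two-sided, p = 1.81e-62). The 120 treats all 344909 tested bins as equally likely to be listed. Bins were not matched on read count, so bins with many reads may raise the overlap. They also shared 481 of the 533 RARS1 genes, but 8572 genes were listed after SRRM2 knockdown and no chance value for genes was computed. The RARS bin at 167921742, and bins of NDRG1, TFPI and the creatine transporter gene SLC6A8, were higher after RARS1 and lower after SRRM2 knockdown. Of 315 shared bins with a fold, 118 were higher in both and 118 lower in both, against 23.6 and 35.2 for independent lists. A further 63 were higher after RARS1 and lower after SRRM2 knockdown, against 38.5, and 16 the reverse, against 21.6. Among the 164 shared bins outside merged loci, 100 had the same direction, a smaller share than the 236 of 315 over all shared bins with a fold. Agreement in direction was thus more frequent inside merged loci. If both comparisons used the same control libraries, which the column names do not settle, part of the excess may come from the controls. For unchanged groups with the same controls, 9.86 shared bins of equal direction were computed. That is under the 120 for independent lists, so it does not stand for lists of these lengths. It therefore sets no limit on the part that may come from the controls.

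Junction events and exon bins were compared by gene. After SRRM2 knockdown 277 of 295 genes with an event also held a listed bin (93.9%), against 93 of 108 genes with an event only in another table (86.1%, Fisher's exact test, p = 0.0221, adjusted p = 0.0441). After RARS1 knockdown 6 of 37 genes with an event held a listed bin (16.2%), against 7.90% of other genes, with each gene of a merged locus counted as holding its bins (Fisher's exact test, p = 0.0689, adjusted p = 0.0689). FGFR3 after RARS1 knockdown and MAP3K7 and FTCD after SRRM2 knockdown were among the genes with both.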

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

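Every test in this part on explanations was chosen after the results were seen, and the comparison of directions between knockdowns was likewise not planned. Retained introns changed in different directions between knockdowns: 16 of 16 rose after RARS1 knockdown and 12 of 156 after SRRM2 knockdown (Fisher's exact test, adjusted p = 1.34e-14). Against MARS1 knockdown, where 16 of 65 rose, the RARS1 share also differed (Fisher's exact test, adjusted p = 5.37e-08). The SRRM2 and MARS1 shares differed as well, though both lay under 50% (Fisher's exact test, adjusted p = 0.00165). For cassette exons, the share that rose was 29.2% after RARS1 knockdown, against 76.7% after SRRM2 (Fisher's exact test, adjusted p = 1.61e-05) and 70.4% after MARS1 knockdown (Fisher's exact test, adjusted p = 0.000893).

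The opposite direction of retained introns argues against chance values of the shared control libraries, which would move all knockdowns the same way. The RARS1 and SRRM2 shares lay on opposite sides of 50% (Fisher's exact test, adjusted p = 1.34e-14). This is the test that flagged the pattern and not a separate one. It counts events as independent and does not measure the spread between libraries. A library batch stays open: the lowest trimming loss of the 6 SRRM2 and MARS1 libraries was 5.68 times the highest of the 6 others, and this split cannot be told apart from the knockdowns. A difference between loss of a splicing protein and of a synthetase is a biological explanation that remains untested, and the fall after MARS1 knockdown does not follow that line.

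Usage after SRRM2 knockdown was lower in most listed bins. Coverage shifted toward the 3′ end may contribute, since genes with at least 5 listed bins had a median rho of 0.18 with position. In the last of 5 parts, nearest the 3′ end, 48.0% of bins were higher (95% interval 47.1% to 49.0%). Position here is the rank among a gene's listed bins and not the place in the gene. This share therefore cannot decide whether such a shift is the whole cause. Overlapping genes do not account for the lower usage, as 38.1% of bins were higher once merged loci were left out. A candidate explanation for part of it is loss of retained-intron sequence, as 90% of 1-transcript bins were lower in genes with a falling intron. Those genes were chosen by the same knockdown, and such bins may hold the intron itself, so this is not independent support. Bins of more transcripts were also lower in 59.1% of cases. Bins were not marked as intron or exon, and these bins may hold intron sequence too. Their share therefore cannot decide whether intron loss is the whole cause. The unmatched control columns of that table leave a difference between control sets open.

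Of the bins listed after RARS1 knockdown, 47.2% lay in merged loci, against 23.6% after SRRM2 knockdown (Fisher's exact test, p = 4.99e-57). A change in the expression ratio of overlapping genes may explain these bins, since in 17 of 18 loci with at least 3 assigned bins the bins split by the gene that holds them. After SRRM2 knockdown 141 of 345 such loci split this way, against at most 35 in 1000 shuffles, which treat bins of the same gene as independent. Which of the remaining bins reflect splicing was not tested.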

How the results depend on the processing

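Counts moved with their thresholds. With a change of at least 20 points, 3, 83 and 34 junction events remained listed after RARS1, SRRM2 and MARS1 knockdown, by construction. With an adjusted p under 0.01 the exon tables held 456 and 20574 bins, with an absolute log2 fold of at least 1 203 and 9610, and without merged loci the RARS1 table held 522. The share of RARS1 bins with higher usage passed the test at 61.6% with that fold and at 59.8% without merged loci, and lay at 49.7% with a mean count of at least 50; the cause was not tested. At 20 points the direction of retained introns no longer passed for RARS1 (100%, 2 events) or MARS1 (38.1%), nor did that of MARS1 cassette exons (69.2%), where fewer events were tested, and RARS1 and SRRM2 shared 0 junction genes. The number of RARS1 gene lists past the threshold, 0, became 2 with Fisher's exact test and 1 without merged loci. Leaving out each library in turn turned the sign of the small RARS1 differences from control in unique reads (-7.36 to 0.930 M reads), trimming loss (-0.0102 to 0.00247 percentage points) and unique share (-0.0417 to 0.505 percentage points), and of no SRRM2 or MARS1 difference. With the replicate block, 837 RARS1 bins had all 3 same-numbered pairs in the direction of usage (12.5% by chance), against 724 with separate groups (5%), which implies the former, so this does not test the block. Chosen after seeing the data were the alternatives without merged loci for overlaps and lists, those with repeated rows or all protein-coding genes, loci with at least 2 assigned bins, and the replicate block and left-out libraries of the RARS1 counts. Not run, because the tables list only called bins or 1 value per group, were an adjusted p under 0.1, other normalisation, blocked or left-out-library refits and a stricter junction probability.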

Other observations

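No test was run for this part, and CDK1, PCBP2 and DNM1L were chosen only after their values were seen. The MARS bins with higher usage after SRRM2 knockdown included the 3′ most listed bins of the gene. In the authors' deposited table the bin at chromosome 12, 57911066 to 57911352 (GRCh37), had a log2 usage of 1.90 (adjusted p = 1.73e-09) at a mean count of 274. In RARS the bins at 167919853, 167921742 and 167924017, which rose after RARS1 knockdown, had log2 usage of -0.95, -1.05 and -1.11 after SRRM2 knockdown in the authors' deposited table. An alternative splice site of the cyclin-dependent kinase gene CDK1 was at 12.6% in the control and 27.8% after SRRM2 knockdown in the authors' deposited table. One of PCBP2, which encodes a poly(C)-binding hnRNP, rose from 19.3% to 33.1% after SRRM2 and from 19.4% to 34.0% after MARS1 knockdown in the authors' deposited table. In the mitochondrial fission gene DNM1L a cassette exon rose from 38.0% to 56.3% after SRRM2 and from 38.1% to 52.6% after MARS1 knockdown in the authors' deposited table.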
